A study of Mus musculus with 2 samples.

How the data were processed

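Bone marrow cells of C57BL/6 mice, an inbred laboratory strain, were stained for Gr-1 (an antigen of granulocytes, though not of them alone) and CD48 (an antigen of many other blood cells). Live Gr-1-high, CD48-negative neutrophils were sorted by flow cytometry in 2 independent experiments, per the labels' protocols. Total RNA was extracted, 200 ng was turned into biotin-labelled cRNA with an Affymetrix 3' IVT kit and hybridised to 1 expression array per experiment, per the labels' protocols. The study therefore holds 1 group of 2 samples, called replicate 1 and replicate 2 after their titles. Whether each sample came from 1 mouse or a pool is not given in the sources used here.

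The deposited table holds a linear signal intensity for each of 45101 probe sets on each array. The values were made by the authors with MAS5, per the submitters' processing notes; its version and settings are not given in the sources used here. MAS5 summarises the probe pairs of a probe set into 1 signal and multiplies each array by 1 factor. Checked on the values, the mean signal without the lowest and highest 2% of probe sets was 250.0 on both arrays, so the total brightness of the arrays had been made equal before deposit, and a difference between arrays is relative to that scaling. The table used here holds no detection calls or scale factors. The number of arrays, 2, limits the precision.

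Probe sets were named from GEO's platform annotation: 34958 had 1 gene, 932 had several genes and 9211 were unnamed here. These counts include 64 control probe sets, and those with a gene name were not kept out of the genes. Of the probe sets with 1 gene, 34754 had their gene identifier in the NCBI mouse gene table (assembly GRCm38.p6), and no symbol changed through it. This gave 18194 genes. No gene was named from a probe set with several genes. Before the data were examined, 33 gene lists with 370 genes were fixed (neutrophil proteins, cellular processes, markers of other marrow cell types, and genes of other organs). Of these genes, 328 had a probe set of their own and 42 were not analysed here.

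Background was read from 87 probe sets of 78 olfactory, vomeronasal, trace amine and taste receptor genes. A probe set was called above background when its signal exceeded their 95th percentile on both arrays (a signal of 108 on replicate 1 and 131 on replicate 2). A gene was above background when at least 1 of its probe sets was. The gene's level is the log2 signal, floored at 1, of its brightest probe set, given as mean ± SD over the 2 arrays. Probe sets bind their targets with different strengths, so no gene's level was compared with another's. Each list's share of genes above background was compared with that of the list of genes of other organs by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 32 lists. Genes are not replicates, so this test describes lists on these arrays. A list that passed had a larger share than the genes of other organs, which need not be larger than the share of all measured genes.

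Differences between the arrays are log2 signal of replicate 2 minus replicate 1. With 1 array per experiment they have no replicate check and no p-value. A list's median difference was placed among the medians of 10000 random lists of the same size, drawn from genes of the same mean level (10 bins), over lists with at least 4 genes above background. Arrays of 7354 genes were simulated with noise set to the whole spread of the observed difference (SD 0.51), drawn independently for each gene. Any real differences between the experiments are therefore counted in that noise. Lists of 10 genes lay outside the central 95% of random lists in 6% of unchanged lists. The share was 26% of lists shifted by 0.5 and 98% of lists shifted by 1 on the log2 scale. Single genes changed by 1 and by 2 on the log2 scale passed a 2-fold difference in 57% and 96% of cases, and 4.72% of unchanged genes did. The 4.72% follows from the spread put in and is not an error rate for the observed genes. The other rates hold for that noise only. In a simulation of detection, 2.46% of background probe sets and 99.6% of expressed probe sets were called above background. The background values were drawn from the same sensory receptor probe sets that set the threshold, and the expressed values lay mostly far above it. These rates therefore check the procedure only and do not tell how often genes near the threshold were missed.

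The named genes follow a rule fixed together with the lists: the first 4 measured members of each list in a fixed order, up to 4 members whose call goes against that of over 75% of their list, and the 10 genes in each direction with the largest difference between the arrays. Other genes are marked where they appear. The alternatives were another background percentile or list, median scaling, quantile normalization, no filter on background, 32 added to the signal, leaving out probe sets whose names end in _x_at or _s_at (which can bind several transcripts), another rule for genes with several probe sets, and each array alone. Scaling to the hybridisation controls, and a filter on the brightest probe set, were added after seeing the data, as were 15 gene families taken by symbol and short lists of early neutrophil, mature neutrophil and abundant monocyte genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.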

Results

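The data describe the transcriptome of neutrophils sorted from the bone marrow of C57BL/6 mice, measured on 2 expression arrays from independent experiments, replicate 1 and replicate 2. The labels give 1 group and no treatment, so the values answer which genes were above background in these cells and how far the experiments differed. Each array held 45101 probe sets. The median signal was 65.5 on replicate 1 and 71.6 on replicate 2. On replicate 1, 17185 probe sets (38.1%) were above the background of that array, and on replicate 2, 16003 (35.5%). Both arrays had 14643 probe sets (32.5%) above background, which covered 7354 of 18194 genes. Of the 87 sensory receptor probe sets that set the background, 2 were above it on both arrays.

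Genes for the proteins that fill neutrophil granules and cytosol were mostly above background, except those of the primary granule. All 10 measured genes of secondary granules were above it, among them Ltf (lactoferrin) at a log2 signal of 14.62 ± 0.58 (SD, n = 2), Camp (cathelicidin) at 14.97 ± 0.40 (SD, n = 2), Lcn2 (lipocalin 2) at 15.12 ± 0.37 (SD, n = 2) and Ngp at 15.09 ± 0.41 (SD, n = 2). All 7 cytosolic neutrophil genes were above background, with the calcium-binding alarmins S100a8 at 15.57 ± 0.58 and S100a9 at 15.21 ± 0.53 (SD, n = 2), Anxa1 at 15.23 ± 0.41 (SD, n = 2) and Padi4, the histone-citrullinating enzyme, at 11.99 ± 0.02 (SD, n = 2). Of the primary granule genes, Ctsc, which encodes the protease that activates the granule serine proteases, was the only one of 5 above background on both arrays, with signals of 771 and 306 on replicates 1 and 2. Mpo (myeloperoxidase) had signals of 98.2 and 187 and was above background on replicate 2 alone. Elane (neutrophil elastase) had 57.7 and 39.2, Prtn3 (proteinase 3) 40.7 and 28.1, and Ctsg (cathepsin G) 10.5 and 2.76, none above background on either array. Of the gelatinase granule and secretory vesicle genes 5 of 7 were above background, including the gelatinase Mmp9 at 14.88 ± 0.13 (SD, n = 2) and the integrin gene Itgam at 12.74 ± 0.01 (SD, n = 2). Against the genes of other organs, of which 2 of 36 were above background (Mbp and Slc34a1), the adjusted p of Fisher's exact test was 1.3e-07 for secondary granules, 5.11e-06 for cytosolic genes, 0.000893 for gelatinase granules and 0.459 for primary granules.

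Effector and receptor genes were also above background. All 6 measured genes of the NADPH oxidase list, which holds subunits of this superoxide-making enzyme and the proton channel gene Hvcn1, were above it, with Cybb at 14.27 ± 0.62, Cyba at 13.57 ± 0.13 and Ncf1 at 14.14 ± 0.27 (SD, n = 2). So were all 13 pattern recognition and Fc receptor genes, including Tlr2 at 10.18 ± 0.86, Tlr4 at 9.46 ± 0.58 and Clec7a (the beta-glucan receptor) at 12.59 ± 1.05 (SD, n = 2). Of the chemoattractant and adhesion receptor genes 11 of 12 were above background, with Cxcr2 at 12.24 ± 0.82, the G-CSF receptor gene Csf3r at 12.57 ± 0.54 and Cxcr4 at 11.62 ± 0.22 (SD, n = 2), while Ptafr was above it on replicate 1 alone (114 and 36.4). Among 10 transcription factor genes of granulopoiesis 7 were above background, including Cebpb at 12.10 ± 0.79, Cebpd at 12.84 ± 0.18 and Gfi1 at 8.31 ± 1.16 (SD, n = 2). The lamin B receptor gene Lbr, whose product shapes the lobed nucleus, had 14.18 ± 0.05 (SD, n = 2), and 7 of 8 nuclear envelope genes were above background. In eicosanoid synthesis 5 of 7 genes were above it, with Alox5ap at 14.47 ± 0.21 and Lta4h at 13.07 ± 0.95 (SD, n = 2). The adjusted p of Fisher's exact test was 1.71e-05 for the oxidase, 4.27e-09 for pattern and Fc receptors, 2.52e-07 for chemoattractant receptors, 0.000173 for transcription factors, 2.08e-05 for the nuclear envelope and 0.000893 for eicosanoids. Ly6g and Cebpe were not analysed here.

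Genes of general processes were above background in most members of each list. All 14 genes of glycolysis and all 15 of the respiratory chain and ATP synthase were above it (adjusted p of Fisher's exact test 2.05e-09 and 1.36e-09). Of the immediate-early and heat shock genes 13 of 16 were above background, including Fos at 13.69 ± 0.28 and Egr1 at 12.07 ± 0.64 (SD, n = 2), and of the cytokine genes 9 of 11, including Il1b at 12.35 ± 1.00 and Cxcl2 at 11.58 ± 1.11 (SD, n = 2). Il6 and Il1a were not above background. The exact adjusted p was 4.25e-07 for immediate-early genes and 7.15e-06 for cytokines. Of the apoptosis genes 8 of 9 were above background (exact adjusted p = 7.15e-06), with the survival gene Mcl1 at 14.55 ± 0.04 (SD, n = 2) and Bcl2 not above it. Of the interferon-induced genes 5 of 9 were above it (exact adjusted p = 0.00363), and of the proliferation genes 11 of 20 (exact adjusted p = 0.000156). These tests are against the genes of other organs, and neither list was compared with all measured genes, of which 7354 of 18194 were above background. The Y-linked genes Eif2s3y, Kdm5d and Uty were above background, and Xist, which is transcribed from the inactive X chromosome, was above it on replicate 2 alone, with signals of 107 and 176. The sex-linked list passed with 3 of 4 genes (exact adjusted p = 0.00731) but not without probe sets that can bind several transcripts (2 of 4, exact adjusted p = 0.0844). Together 150 of 184 genes (81.5%) of the neutrophil and process lists were above background, and 17 of these 19 lists passed. The list of sort antigens held 1 measured gene, Cd48, which was not above background (signals 3.31 and 41.2).

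**Figure D1:**
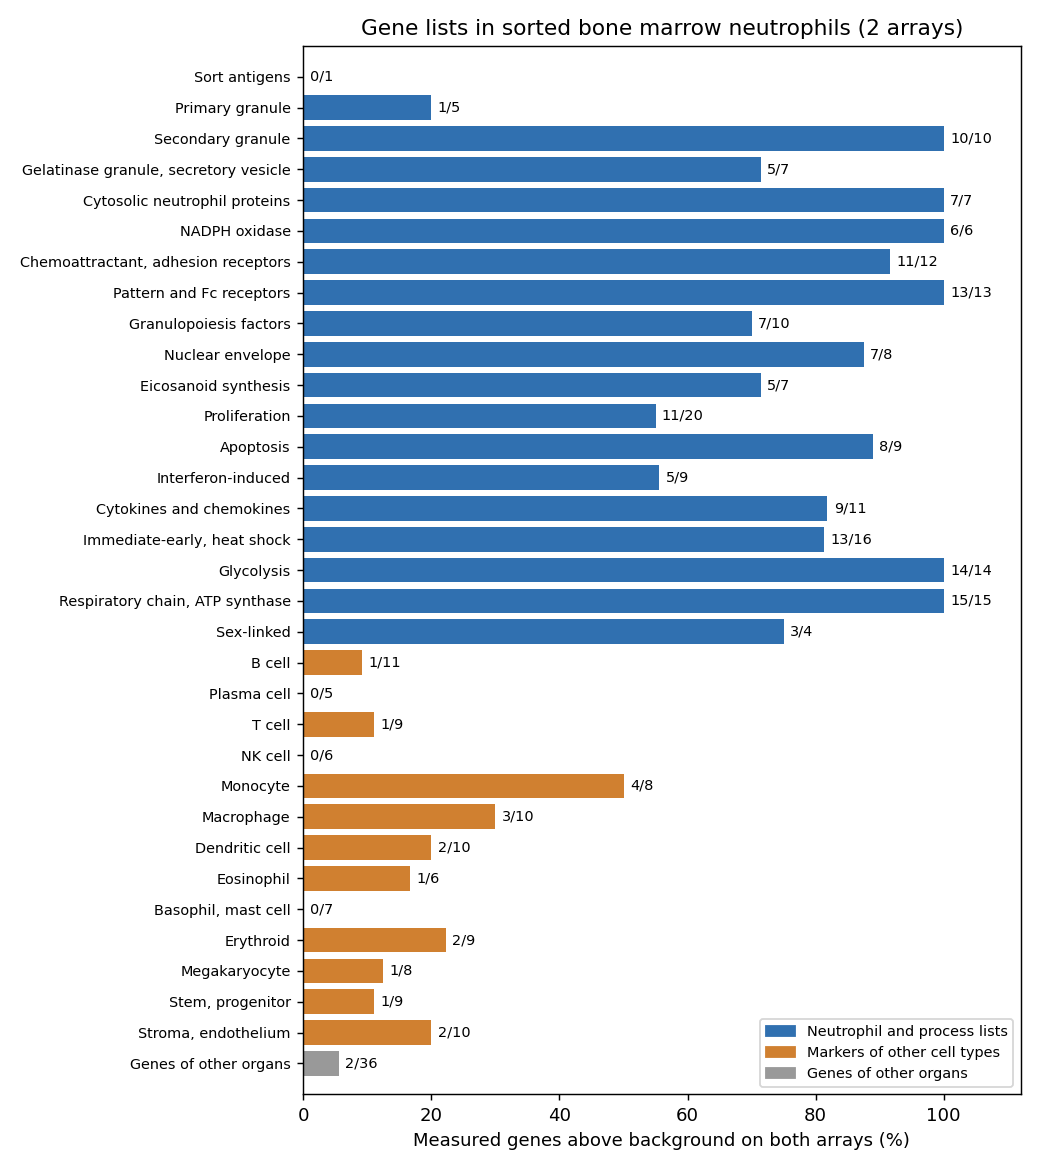
Bars give the percentage of measured genes of each list above background on both arrays, with the counts beside them, for neutrophil and process lists, markers of other cell types and genes of other organs. The neutrophil and process lists reach 81.5% together, the other cell types 16.7% and the genes of other organs 5.56%.

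Markers of other marrow cells were above background in 18 of 108 genes (16.7%), and 1 of the 13 lists passed. That list was the monocyte list, with 4 of 8 genes (exact adjusted p = 0.0116 against the genes of other organs). It was not compared with all measured genes, of which 7354 of 18194 were above background, so passing does not set it apart from them. Its genes above background included Csf1r (the receptor for M-CSF) at 11.60 ± 0.98, Ccr2 at 7.54 ± 0.35 and F13a1 at 7.95 ± 0.14 (SD, n = 2). Of the macrophage markers 3 of 10 were above background, including Adgre1 and C1qb (exact adjusted p = 0.102), and of the dendritic cell markers 2 of 10, Zbtb46 and Cd74 (exact adjusted p = 0.293). The B cell list had 1 of 11, Igll1, the T cell list 1 of 9, Cd3d, the eosinophil list 1 of 6, Siglecf, the megakaryocyte list 1 of 8, Itga2b, the stem and progenitor list 1 of 9, Kit, and the stroma and endothelium list 2 of 10, Kdr and Col1a2. The exact adjusted p was 0.64 for B cells, 0.589 for T cells, megakaryocytes and progenitors, 0.504 for eosinophils and 0.293 for stroma. No measured plasma cell (5), NK cell (6) or basophil and mast cell (7) marker was above background on both arrays (exact adjusted p = 1 for each). The erythroid list had 2 of 9, Klf1 and Epor (exact adjusted p = 0.277), and passed on replicate 1 taken alone with 5 of 9 (exact adjusted p = 0.0161). Its globin gene Hba-a1 was not above background on its own probe set, yet 4 probe sets assigned to several adult haemoglobin genes had signals of 977 to 10964 on replicate 1 and 712 to 8762 on replicate 2, so the list does not show that globin RNA was missing.

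Over the 14643 probe sets above background on both, Pearson's r of log2 signal was 0.953 and Spearman's rho 0.925, the SD of the difference was 0.49, and 4.77% differed over 2-fold. Within narrower ranges of level, without the control probe sets, rho was 0.295 over the 4864 dimmest, 0.483 over the middle 4863 and 0.877 over the 4864 brightest. These are values across probe sets, which are not independent replicates. Over all probe sets, with the dim ones included, r was 0.885, rho 0.888, the SD 1.30 and the share over 2-fold 30.9%. The labels call the experiments independent without giving the number of animals, so the spread between the arrays holds everything that differed between them.

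**Figure D2:**
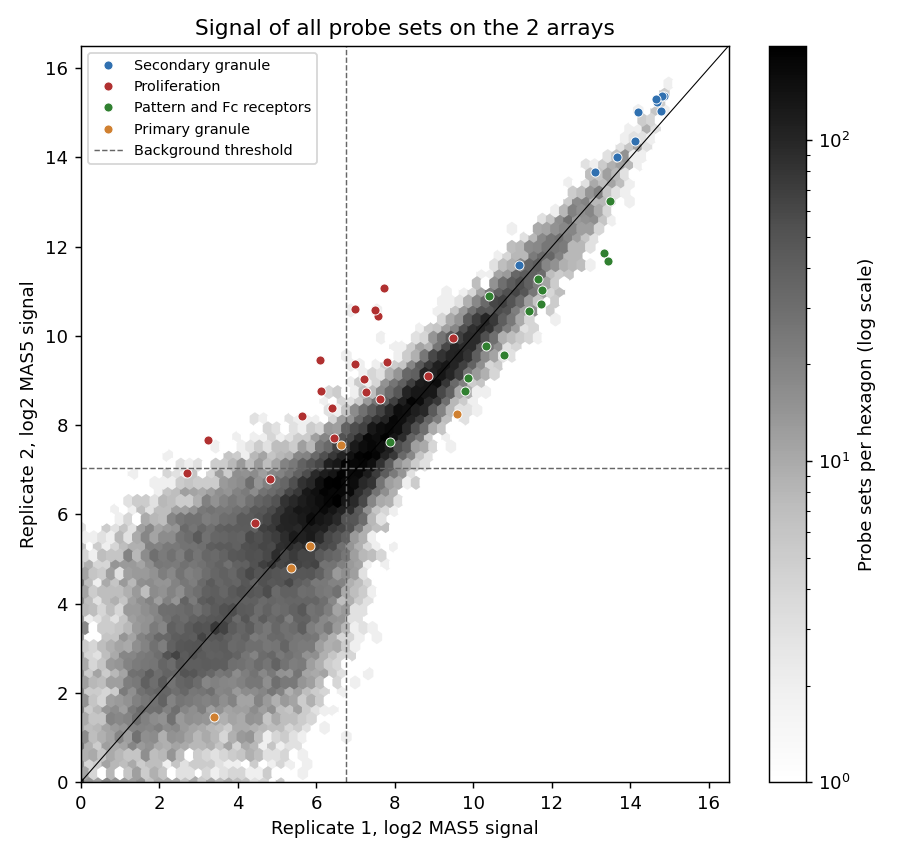
Each hexagon counts probe sets by log2 MAS5 signal on replicate 1 (horizontal) and replicate 2 (vertical), coloured points are the genes of 4 lists, dashed lines mark background and the solid line marks equal signal. Proliferation genes lie above the line of equal signal, 20 of 20 with those below background included, and the 10 secondary granule genes lie close above it.

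Genes of cell division were higher on replicate 2. Mki67, a marker of cycling cells, was 10.2-fold higher (signals 212 and 2149), Top2a, the topoisomerase of dividing cells, 7.40-fold, the cyclin gene Ccnb2 5.23-fold, and Cdk1, below background on replicate 1, at least 6.54-fold. All 11 proliferation genes above background on both arrays were higher on replicate 2, with a median log2 difference of 1.82, beyond the central 95% of 10000 random lists matched on level (-0.22 to 0.42). Of these 11 genes, 8 were over 2-fold higher. Of the other 9 measured members, 6 were above background on replicate 2 alone, 4 of them at least 2-fold higher by their bound, and 3 were above background on neither array. Among genes above background on both arrays, which leaves out Cdk1, the 10 with the highest measured differences in this direction were Kif22 (13.2-fold), Cks1b (12.6-fold), Cdc20 (12.3-fold), Mki67, Rrm2 (8.41-fold), Top2a, Cdca5, Cdca8 (6.35-fold), Ube2c (5.52-fold) and Cdkn3 (5.37-fold). Cdca5 ranked there through a replicate 1 signal below background (51.3), and its bound of at least 3.18-fold does not support that place. On replicate 1 Cks1b (116), Cdc20 (127), Cdkn3 (122) and Ccnb2 (126) lay close above the background of 108, so their folds are uncertain. Kif22, Cdc20, Rrm2 and Cdca8 were read on _x_at or _s_at probe sets. Of the 3 probe sets of Kif22, 1 was above background on both arrays. Gfi1, a repressor needed for granulocyte differentiation, was 3.11-fold higher on replicate 2. The secondary granule genes were higher in 10 of 10 (median 0.55), the cytosolic neutrophil genes in 5 of 7 (0.57) and the respiratory chain genes in 13 of 15 (0.43), all beyond their random lists, and all 3 medians were below 0 after scaling to the hybridisation controls (-0.17, -0.14 and -0.29), where the median of all genes was -0.65. Quantile normalization brought the secondary granule and cytosolic lists inside the random interval, with medians of 0.18 and 0.06, where the median of all genes was 0.05. The brightest signals were higher on replicate 2, with a maximum of 47382 on replicate 1 and 78810 on replicate 2. The 100 brightest probe sets held 11.8% and 14.6% of the signal. Many genes of these 2 lists are among the brightest, which the 10 bins of level do not match closely.

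Receptor, cytokine and immediate-early genes were lower on replicate 2. Among the pattern and Fc receptors 12 of 13 were lower, with a median log2 difference of -0.82, including Clec7a at -1.49 and Tlr2 at -1.21. All 9 cytokine and chemokine genes above background were lower (median -0.66), with Cxcl2 at -1.57 and Il1b at -1.41. The interferon-induced genes were lower in 5 of 5 (median -0.84), the immediate-early and heat shock genes in 11 of 13 (-0.68), the chemoattractant and adhesion receptors in 8 of 11 (-0.60), including Cxcr2 at -1.16, and the monocyte markers in 3 of 4 (-0.66), with Csf1r at -1.38. These 6 lists and the 4 that were higher lay outside the central 95% of random lists, 10 of 17. Chance gives 0.85 only if the genes of a list, and the lists, vary independently of each other. This was not tested, so the count does not measure an excess over chance. Without a background filter the monocyte median was 0.15. The 7 lists inside the interval were glycolysis (0.20), the NADPH oxidase (0.28), eicosanoid synthesis (0.23), the nuclear envelope (0.07), gelatinase granules (0.01), granulopoiesis factors (-0.13) and apoptosis (-0.20). The 10 genes with the greatest differences in favour of replicate 1 were Slc2a6 (4.49-fold higher there), St3gal6 (4.03-fold), St8sia4 (3.71-fold), 5430427O19Rik (3.70-fold), Arg2 (3.52-fold), Il13ra1 (3.47-fold), Clec4d (3.36-fold), Wfdc17 (3.33-fold), Ccl6 (3.23-fold) and Trps1 (3.22-fold). St3gal6 and St8sia4 encode sialyltransferases, and Arg2 encodes an arginase. In total 404 genes (5.49%) differed over 2-fold, 257 higher on replicate 2 and 147 on replicate 1, a split that became 166 and 238 with median scaling and 33 and 1538 with scaling to the hybridisation controls. These differences compare 1 array per experiment and have no replicate check.

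**Figure D3:**
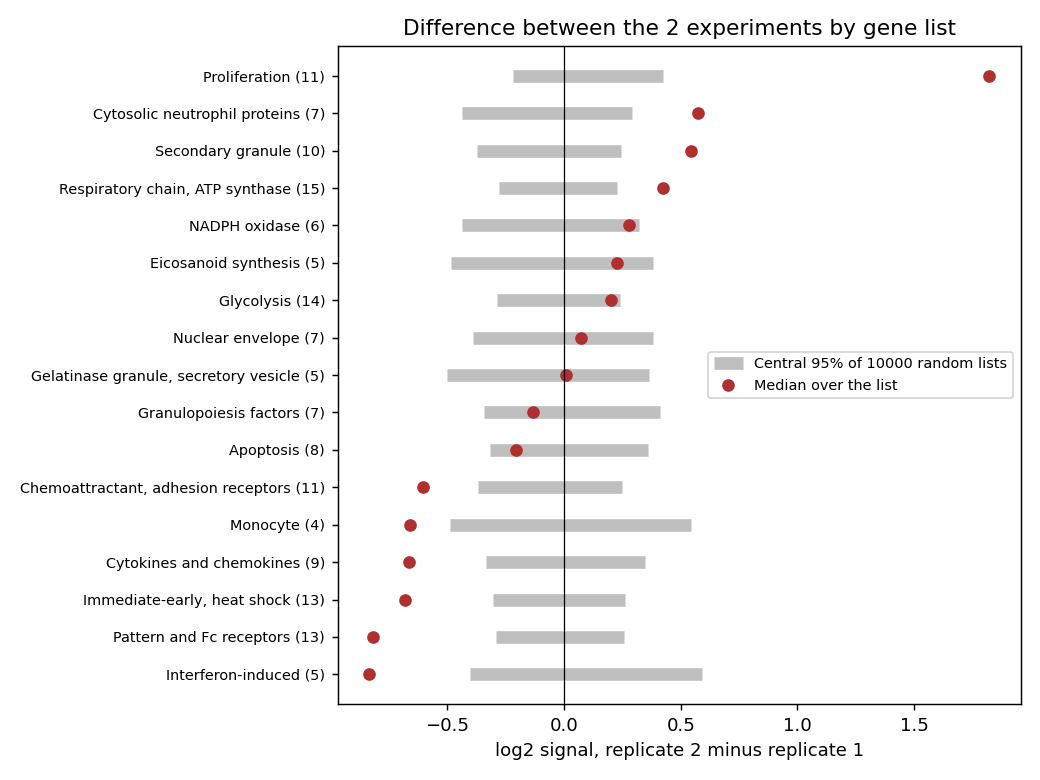
Points give the median log2 difference (replicate 2 minus replicate 1) over the genes of each list above background on both arrays, with their number in brackets, and grey bars give the central 95% of 10000 random lists matched on level. Proliferation lies at 1.82 and the interferon-induced genes at -0.84, and 10 of 17 lists lie outside their bars.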

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

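The test of the sensory receptor probe sets, the tests of B cell, erythroid, progenitor and primary granule genes without a filter, and the second reading of the monocyte genes were chosen after the results were seen; the early, mature and abundant monocyte lists were written after the list results but before the values of their own genes were read. Among the 9160 probe sets that have no gene name here and are not controls, 1766 (19.3%) were above background on both arrays, a signal in data outside the gene lists. No explanation was tested for it.

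Proliferation genes were higher on replicate 2 in 11 of 11 genes above background (median log2 difference 1.82). Amplified background on that array is argued against as the source of a difference of this size. The sensory receptor probe sets differed by a median of 0.13 (bootstrap interval -0.09 to 0.36). This lay under a limit of 0.5 that was itself chosen after the results were seen. Single sensory receptor probe sets varied widely, with an SD of the difference of 1.30. A larger share of immature neutrophils in replicate 2 is a candidate explanation. The early neutrophil list, with no proliferation gene in it, was higher in 12 of 12 genes (median 0.58, random lists -0.33 to 0.24). Its median was -0.14 after scaling to the hybridisation controls, where the median of all genes was -0.65. The mature list was lower in 14 of 14 (median -0.53). Both directions had been written down before the values of these genes were read. The lists were written after the proliferation and granule lists had been seen to be higher and the receptor lists lower. Their directions are therefore no independent check of this candidate. The primary granule genes, made earliest, gave no clear answer: 4 of 5 were lower, with a median of -0.56 inside their random lists (-0.87 to 1.23), and most were below background. Ctsc was at -1.33, while Mpo, above background on replicate 2 alone, was at 0.93. Other dividing marrow cells could not be excluded. The B cell markers had a median of 0.97 at the edge of their interval (-0.61 to 0.97), the stem and progenitor markers 1.00 (-0.61 to 0.92, 6 of 9 higher) and the erythroid markers -0.19. This test lay near background and also placed the genes of other organs (-0.39) outside their interval (-0.29 to 0.58). The 4 bright probe sets shared by haemoglobin genes were lower on replicate 2 in 4 of 4 (median -0.36). They are assigned to the same genes, so they are not separate observations. They show no more globin RNA on replicate 2, which alone does not settle whether dividing erythroid cells were present. The test of B cell and erythroid markers first had separate parts, in which the B cell part passed at the edge of its interval. These parts were merged after their results were seen. The gate would remove the other marrow cell types as far as they lack high Gr-1 or carry CD48. Cd79a was at 17.6 and 111, below background on both arrays, and Kit, above it on both, was at 244 and 547.

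Receptor, cytokine and immediate-early genes were lower on replicate 2. Induction during handling of replicate 1 with no other difference needs the mature neutrophil list, which was not chosen as inducible, to stay unmoved. It had a median of -0.53 (random lists -0.33 to 0.22). That does not decide the question, because the list also holds genes of interferon-induced proteins, Ifitm1 (-1.41) and Ifitm2 (-0.96). It was also written after the receptor and cytokine lists had been seen to be lower. Monocytes among the sorted cells of replicate 1 may contribute. The reading written down before these values were seen, over the 6 abundant monocyte genes above background, gave -0.95 (random lists -0.32 to 0.46), which is what they predict. Among these 6, Irf5 was at -1.21 on its brightest probe set, below background on replicate 2. Its 1 probe set above background on both arrays was higher on replicate 2. The gate would remove monocytes as far as they lack high Gr-1 or carry CD48, and Cd48 was above background on neither array. A second reading over all 10 measured genes, added after the first was seen, gave -0.39 (random lists -0.34 to 0.53, 8 of 10 lower). This fell short of the -0.5 written down for monocytes and leaves their contribution open. Of these 10, S100a4 (102 and 120), Ms4a6c, Ms4a6b and Ms4a6d were not above background, while Cst3, Tgfbi and Ctss are also expressed by neutrophils. Ccr2, which stands in the other monocyte list, was at 157 and 220. The larger share of immature neutrophils in replicate 2, a candidate given above, was not tested for the receptor, cytokine and immediate-early genes and stays open for them. With 1 array per experiment, a batch effect and a difference between experiments cannot be told apart.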

How the results depend on the processing

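Scaling to the hybridisation controls and the filter on the brightest probe set were chosen after seeing the data. No paired analysis was possible because the labels give 1 group only, and no array could be left out of a difference between 2 arrays. Leaving out each array in turn gave 16003 to 17185 probe sets above background, 18 to 19 lists passing and a median gene level of 8.929 to 9.002. The other background settings gave 11360 to 16763 probe sets, with 18 lists at the 90th and 99th percentiles, and leaving out _x_at and _s_at probe sets gave 17 lists. Lists outside the random interval numbered 8 with quantile normalization and 10 with the other settings that keep a background filter. With no background filter 13 lay outside, but out of a larger set of lists. These 13 held the B cell, dendritic cell, stem and progenitor and other organ lists, which are not among the 17 lists compared as deposited. The monocyte list, outside as deposited, lay inside. Genes over 2-fold, higher on replicate 2 and on replicate 1, numbered 166 and 238 with median scaling, 2911 and 2166 with no background filter, 33 and 1538 with scaling to the hybridisation controls, and 414 and 296 with the median over the probe sets of a gene, which also moved the median gene level to 8.11. With no background filter the SD of the difference was 1.30, Spearman's rho 0.888, the share over 2-fold 30.9% and the monocyte median 0.15. Adding 32 to the signal gave an SD of 0.453 and 3.47% over 2-fold, leaving out _x_at and _s_at probe sets a rho of 0.920, and scaling to the hybridisation controls 23.5% over 2-fold. That last scaling moved the median of all genes to -0.65, and with it the sign of the medians of secondary granule (-0.17), cytosolic (-0.14), respiratory chain (-0.29), early neutrophil (-0.14), ribosomal protein (-0.39), proteasome (-0.41), chaperonin (-0.15) and tRNA synthetase genes (-0.19), which all lay above their random lists. The cause of the other changes was not tested. Signal near background limits the dim markers: among probe sets not above it on both arrays, 43.5% differed over 2-fold.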

Other observations

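The 15 gene families described here, and the genes named from them, were chosen after the list results were seen, so their tests are descriptions of these arrays. Ribosomal protein genes were higher on replicate 2 in 39 of 42 (median log2 difference 0.32), the chaperonin subunit genes, which fold actin and tubulin, in 8 of 8 (0.57), with Cct2 at 0.75 and Cct6a at 0.83, and the aminoacyl-tRNA synthetase genes in 10 of 10 (0.53), with Kars at 1.13. Proteasome subunit genes were higher in 32 of 37 (0.30). These 4 medians lay above their random lists, and all were below 0 after scaling to the hybridisation controls (-0.39, -0.15, -0.19 and -0.41), which lowered the median of all genes to -0.65. Genes with Smc and Ncap symbols, which encode condensin and cohesin subunits and, for Smc5 and Smc6, a DNA repair complex, were higher in 9 of 10 (0.84), with Smc2 at 2.28 and Ncaph at 1.91, and stayed above 0 with that scaling (0.09).

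Toll-like receptor genes were lower on replicate 2 in 5 of 7 (median -0.85), with Tlr1 at -1.36, but 4 of them (Tlr2, Tlr4, Tlr6 and Tlr13) also stand in the pattern and Fc receptor list, and of the others Tlr5 (0.12) and Tlr7 (0.67) were higher. Also lower were genes with interleukin receptor symbols, including the receptor antagonist gene Il1rn, in 10 of 12 (-0.55), with the decoy receptor gene Il1r2 at -0.97 and Il4ra at -0.89, where Il1r2, Il1rn and Il17ra also stand in other lists. Both medians lay below their random lists. The other 8 families lay inside as deposited: kinesins (0.18), MCM and origin licensing (0.37), tubulins (0.35), vacuolar ATPase (0.07), solute carriers (0.03), guanylate-binding and Ifi genes (-0.14), genes with H2 symbols taken as MHC class I, which also hold H2-DMb2 and H2-Ke6 from outside that class (-0.21), and C-type lectins (-0.24). Of these, kinesins (0.55) and the H2 genes (-0.29) lay outside with no background filter, and the H2 genes (-0.41) and tubulins (0.40) with the median over the probe sets of a gene.

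The control transcripts were brighter on replicate 2. The 9 hybridisation control probe sets were higher by a median log2 difference of 0.70 (1.63-fold), the 12 poly-A control probe sets by 0.95 and the 18S rRNA probe sets by 0.47. The ratio of 3' to 5' signal was 0.762 and 0.783 for Gapdh and 1.10 and 1.25 for Actb on replicates 1 and 2. The 4 probe sets shared by adult haemoglobin genes were lower on replicate 2 in 4 of 4 (median -0.36), and 1 probe set shared by Ly6c paralogues had signals of 14393 and 17360.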
